A study of Homo sapiens with 4 samples.

How the data were processed

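Chromatin bound by p53 was profiled by ChIP-seq in H1299, an established human lung carcinoma cell line without p53 of its own, in which wild-type p53 (p53WT) or a mutant form named CASM34 in the labels was expressed. There were 4 libraries, 2 per group, and each was numbered 1 or 2 in its title. Per the labels' protocols, chromatin was cut with micrococcal nuclease and sonicated, then precipitated with the p53 antibody DO-1. Nothing in the labels says whether the replicates came from separate cultures. Tests of group means therefore measure only the spread between these libraries, which may be technical. All other tests run over genes or regions and hold no spread between libraries.

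The submitters' processing notes name Trim Galore, Bowtie2, bedtools and the genome build GRCh38. The peak caller, any control library and the calling threshold are not given in the sources used here. The deposited lists hold 1 set of peaks per library, and replicates were not pooled. Each row gives a start, an end and a summit, a fold, that is the ratio of signal over background as the authors' caller gave it, a deposited −log10 p and −log10 q, and a deposited score that follows the −log10 q. The smallest deposited −log10 q in the lists corresponded to a q-value of 0.05. All these values are the authors' own and were used only to describe, rank or filter peaks within a list. The lists carry no read counts, so the depth of each library is unknown. A list that lacks a peak does not show that p53 was absent there.

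Rows with the same interval were counted once, with the summit of the highest −log10 p. Peaks on chromosomes 1 to 22, X and Y were analysed, and those on other sequences were set apart. Peaks were compared by an overlap of at least 1 bp. Overlap expected by chance came from 100 random placements of the peaks on their own chromosomes and, as a choice made after seeing the data, from 100 placements within 500 kb of each peak. Both were also drawn for each direction of a pair, and the highest value is given. Peaks of the 4 libraries were merged into regions, and a region was group-specific when both libraries of a group and neither of the other called it. The same count was made for the other splits of the 4 libraries into 2 and 2.

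Genes came from a RefSeq table of GRCh38 with 20037 protein-coding genes on the chromosomes used. Its strand, exons and the genome sequence were not used here. The planned distance to a transcription start therefore became the distance to either annotated end of a gene, and exons and introns were not separated. A peak was at a gene end when its summit lay within 1 kb of an end of a protein-coding gene. Other peaks were inside a gene, between genes, or far from genes, meaning outside genes and over 100 kb from the nearest end; this last class was defined after seeing the data. The planned search for p53 response elements, which needs the genome sequence, was not run.

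Lists of genes were fixed before the data were examined, as were the tests, the alternatives not named here as added, and the rule for named genes. They held 305 entries in 12 lists, of which 303 matched the table, 3 of them by an older symbol. A union of the lists of direct protein-coding p53 targets, with 137 genes, was added later, which gives 13 lists. A gene was called when a summit lay within 10 kb of either end. Each list was set against 10000 random draws of genes of the same kind, matched on the number of RefSeq transcripts and on gene length in place of the planned number of starts. Such a draw permutes list membership among matched genes, and the one-sided p is called a permutation p; it treats genes as independent and compares a list with other genes in 1 library, not the conditions. Benjamini-Hochberg adjustment covered the 13 lists within a library. The smallest p that 10000 draws can give is 0.0001.

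The rule named CDKN1A and MDM2; direct targets with a peak in all 4 libraries or in both libraries of 1 group alone, of which there were 0; and the 8 best-ranked regions of each of 3 classes (all 4 libraries, p53WT-specific, CASM34-specific), summarised with examples. Some items that the rule names are not reported here. Other genes are said to be chosen after their values were seen.

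Group means were compared with an exact two-sided permutation test, which cannot give a p below 0.333 with 2 libraries against 2. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Genes and regions were compared by exact binomial and Fisher tests, two-sided, which compare these libraries and not the conditions. On simulated peaks with 200 planted regions in each of 5 patterns, between 200 and 203 were found. The simulated peaks were spread evenly over the chromosomes, while many peaks of the real lists are clustered. Among 200 simulated lists of 20 genes, 5.0% of unchanged lists and 99.0% of lists with a 4-fold rate were called at the call rate of p53WT 2. At the call rate of p53WT 1, 17.5% of the lists with a 4-fold rate were called. These simulated lists were judged by an unadjusted permutation p under 0.05, with genes called independently. The rates are therefore not those of the adjusted calls in the results. Alternatives covered stricter q, lists of equal length, all sequences, other overlap rules, other distances, a replicate block and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.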

Results

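Peak lists from p53 ChIP-seq were compared between H1299 cells expressing wild-type p53 (p53WT, 2 libraries) and cells expressing the CASM34 mutant (2 libraries). The design asks where p53 sits on chromatin with each form. The lists held 1604 peaks in p53WT 1, 4961 in p53WT 2, 1712 in CASM34 1 and 3211 in CASM34 2. Read depth was unknown.

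In both groups the library numbered 2 held many more peaks at the ends of protein-coding genes than the library numbered 1. Gene-end peaks numbered 59 in p53WT 1, 1708 in p53WT 2, 78 in CASM34 1 and 1098 in CASM34 2. Within 1 kb of a gene end were 34.4% of the peaks of p53WT 2 (95% interval 33.1 to 35.8) and 34.2% of those of CASM34 2. The shares were 3.68% in p53WT 1 (95% interval 2.81 to 4.72) and 4.56% in CASM34 1. Far from genes, meaning outside genes and over 100 kb from an end, were 1212 peaks (75.6%) of p53WT 1, 1491 (30.1%) of p53WT 2, 1250 (73.0%) of CASM34 1 and 1065 (33.2%) of CASM34 2. These counts differed less between the libraries than the shares did. The gene-end share averaged 19.1% ± 21.7 (SD, n = 2) in p53WT and 19.4% ± 20.96 (SD, n = 2) in CASM34. This difference was far smaller than the spread between replicates (exact two-sided permutation p = 1, smallest possible 0.333). Within number 1 p53WT minus CASM34 was -0.88 percentage points, and within number 2 it was 0.23.

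**Figure D1:**
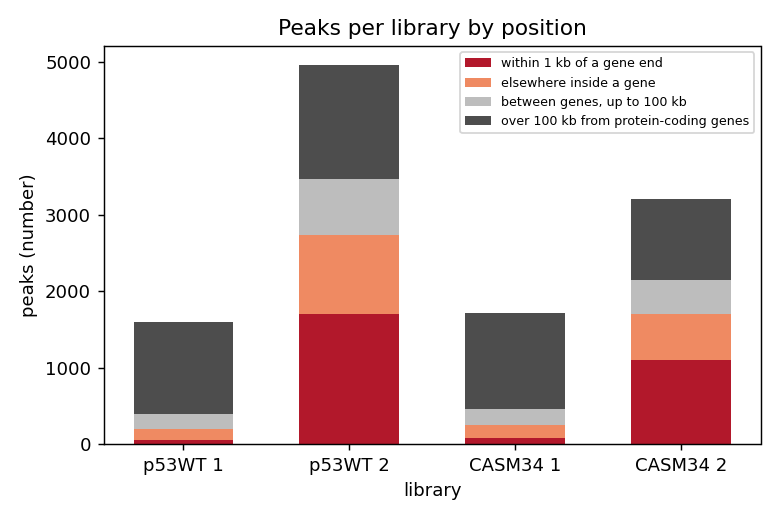
Number of peaks (vertical axis) in each of the 4 libraries (horizontal axis), with each bar divided by the position of the peak summit relative to protein-coding genes. Gene-end peaks make up 34.4% and 34.2% of the libraries numbered 2, and 3.68% and 4.56% of those numbered 1.

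The number of peaks did not separate the groups. It averaged 3282.5 ± 2373.8 (SD, n = 2) in p53WT and 2461.5 ± 1060.0 (SD, n = 2) in CASM34, an exact two-sided permutation p of 1. The difference of 821 peaks turned to -857.5 without p53WT 2, and to -5.5 among peaks with a −log10 q of at least 5. Within number 1 it was -108 peaks, and within number 2 it was 1750.

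Most regions that both p53WT libraries called were also called with CASM34. Of 927 regions in both p53WT libraries, 90.7% (95% interval 88.7 to 92.5) were in at least 1 CASM34 library, and of 888 in both CASM34 libraries, 93.0% (91.1 to 94.6) were in at least 1 p53WT library. All 4 libraries shared 648 of the 7749 regions. Of these 75.2% were far from genes and 2.47% were at a gene end. Their best-ranked members included a region 690.2 kb from the nearest end of WSB1 on chromosome 17 (26603662 to 26604329) and a region 794.1 kb from EMB on chromosome 5 (49601495 to 49602264). After their values were seen, it was noted that members at gene ends included several of the USP17L family, near-identical genes clustered on chromosome 4, so that their peaks are uncertain. Whether the regions shared by all 4 libraries mark bound p53 was not tested. The shares of 90.7% and 93.0% therefore do not show that both forms of p53 bind the same sites.

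Regions specific to a group were few. There were 86 p53WT-specific and 62 CASM34-specific regions, 148 together. The order turned to 52 against 55 and 30 against 35 at a −log10 q of at least 3 and 5, and to 51 against 61 with lists of equal length. The split of the libraries by number separated 694, and the crossed split 156. The p53WT-specific regions were far from genes in 72.1% and the CASM34-specific in 67.7% (Fisher exact test, two-sided, adjusted p = 0.736), and at gene ends in 9.30% and 9.68% (adjusted p = 1). The best-ranked p53WT-specific region lay on chromosome 19 (27059015 to 27059334), 2146.1 kb from UQCRFS1. Others were nearest to TPTE (1426.4 and 1387.2 kb away), ZNF716 (983.2 kb) and ZNF33B (728.5 kb). Another, on chromosome 16 (34572062 to 34572241), lay near a region called in all 4 libraries (34573911 to 34574336). The best-ranked CASM34-specific region lay on chromosome 12 (36397072 to 36397289), 1919.5 kb from ALG10B. Others were nearest to TUBA3C (2045.4 kb away), ZNF37A (1896.4 kb) and ZNF254 (1476.0 kb). UQCRFS1 was also the nearest gene of a CASM34-specific region (chromosome 19, 26917147 to 26917343). At such distances the gene names serve as landmarks only. At gene ends, and chosen after their values were seen, were CDK14, ATP2A2 and RBCK1 among the p53WT-specific regions. RASA2, CCNL1, SNX9, RIOX1 and NAE1 were among the CASM34-specific ones, and were chosen in the same way. Their lowest rank percentiles in the calling lists ran from 8.54 (RBCK1) to 30.3 (CDK14), and from 9.46 (NAE1) to 27.5 (RASA2). Each thus ranked low in at least 1 list, and its absence from the other group does not show a difference in binding. Without p53WT 1 the p53WT-specific count was 3318, and without CASM34 1 the CASM34-specific count was 1640, since a single library then stood for its group.

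**Figure D2:**
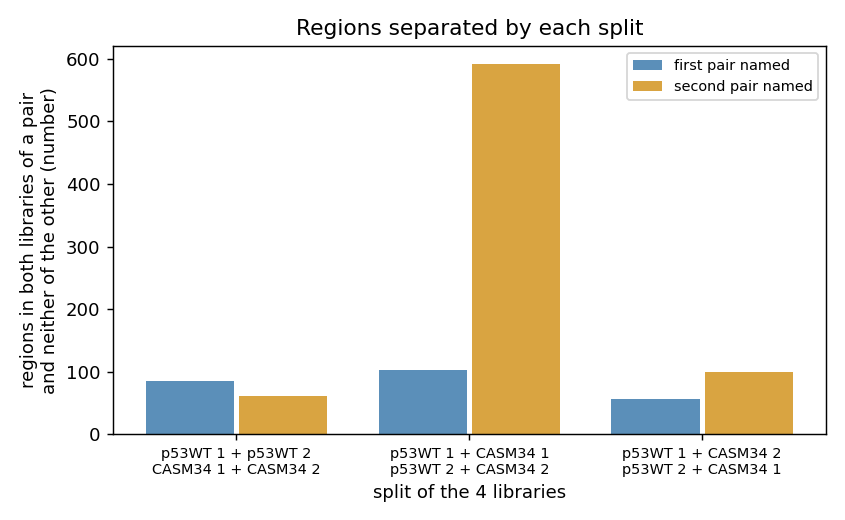
Number of regions called in both libraries of a pair and in neither library of the other pair (vertical axis), for each split of the 4 libraries (horizontal axis). The pair of libraries numbered 2 shares 591 such regions, against 103 for the pair numbered 1, 86 for p53WT and 62 for CASM34; with lists of equal length, which are not drawn, the pairs numbered 2 and 1 share 125 and 158.

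The regions shared by the libraries numbered 2 alone were mostly genic. Their lead in number, 591 against 103 for the libraries numbered 1 alone, turned to 125 against 158 with lists of equal length and to 68 against 79 at a −log10 q of at least 5. Of these 591 regions, 337 (57.0%, 95% interval 52.9 to 61.1) lay at a gene end. Of the 103 regions of the libraries numbered 1 alone, 1 did (Fisher exact test, two-sided, adjusted p = 7.86e-32). The libraries numbered 1 held only 59 and 78 gene-end peaks, so this test restates the shares given above and is no separate support. Regions called in p53WT 2 alone lay at a gene end in 40.4%, and those in CASM34 2 alone in 44.3%. Members of the 591 regions, chosen after their values were seen, included the ends of DNAJC25, LRRK2, ANAPC13 and ARFGEF1. The p53 target RPS27L was also among them, with a region from 63157193 to 63157697 on chromosome 15.

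Overlap of peaks between libraries did not follow the groups. The Jaccard index of covered bases was 0.174 between the p53WT libraries and 0.231 between the CASM34 libraries. Between groups it was 0.407 for the libraries numbered 1, 0.201 for those numbered 2, and 0.231 and 0.178 for the pairs of unlike number. Unlike covered length lowers the ceiling of this index. Peaks covered 463118 bp in p53WT 1 and 1353093 bp in p53WT 2, so 0.407 was out of reach for that pair. CASM34 1 covered 497170 bp, close to p53WT 1. The index was not computed with lists of equal length. In every pair the larger of the shares of peaks that met a peak of the other library was at least 44.4%, against at most 0.467% of the same peaks in random placements and 2.62% in placements near each peak. The share averaged 1.49 percentage points more within groups than between them, less than the SD of 6.62 over the 4 pairs between groups. This difference turned to -2.74 points with lists of equal length and to -1.78 at a −log10 q of at least 5. Pairs share libraries, so no p-value was computed.

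Known p53 targets carried peaks in the libraries numbered 2 of both groups. CDKN1A, the cell cycle inhibitor p21, had a summit in p53WT 2 at chromosome 6, 36678890, inside the gene (36676463 to 36687332). It lay 2427 bp from the nearer end, with a deposited −log10 q of 3.39. In CASM34 2 a peak from 36676192 to 36676642 spanned that end. Its summit at 36676300 lay 163 bp outside the gene, with a deposited −log10 q of 10.7. Another CASM34 2 summit, at 36667422, lay 9041 bp from the same end. MDM2, the ubiquitin ligase that limits p53, had a summit in p53WT 2 at chromosome 12, 68808329, 157 bp inside its end, and was not called in the other libraries. Of 137 direct targets, 32 (23.4%, 95% interval 16.6 to 31.3) had a peak within 10 kb of an end in p53WT 2 against 18.9 among matched random genes (adjusted permutation p = 0.0137), and 26 (19.0%, 12.8 to 26.6) in CASM34 2 against 12.8 (adjusted permutation p = 0.00347). In p53WT 1 the count was 1 and in CASM34 1 it was 2, against 1.20 and 1.51 (adjusted permutation p = 1 in both). Within 50 kb of an end the adjusted permutation p was 0.0536 in p53WT 2, no longer a call, and 0.0225 in CASM34 2. With lists of 1604 peaks each, p53WT 2 had 5 such genes against 4.05 (permutation p = 0.384), and CASM34 2 had 13 (permutation p = 0.0005).

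Genes of cell cycle arrest and p53 feedback passed in both libraries numbered 2, with 10 of 20 in p53WT 2 (adjusted permutation p = 0.0013) and 6 of 20 in CASM34 2 (adjusted permutation p = 0.0166). CDKN1A was called in both. The other arrest and feedback genes named here were chosen after their values were seen. The damage-response gene GADD45A, the death receptor gene TNFRSF10A and TP53INP1 were called in both. PPM1D and PLK2 were called in p53WT 2, and BTG1 in CASM34 2. The lists were kept as fixed, with TNFRSF10A on the arrest and feedback list and the related TNFRSF10B and TNFRSF10D on the apoptosis list. Apoptosis genes passed in CASM34 2 with 8 of 23 (adjusted permutation p = 0.00347) and had 4 of 23 in p53WT 2 (adjusted permutation p = 0.516). Chosen after their values were seen, APAF1 and PERP were in both, BAX, TNFRSF10B, FDXR and TP53I3 in CASM34 2, and BBC3 and DRAM1 in p53WT 2. The peaks of BAX and BBC3 had a −log10 q of 1.40 and 1.35, near the lowest value of 1.31 in both lists. Non-coding RNAs passed in both, with 4 of 13 and 6 of 13 (adjusted permutation p = 0.0436 and 0.0013). Their members were named after their values were seen. PANDAR lies beside CDKN1A and shares its peaks. DINOL lies inside the CDKN1A interval and shares its peak in p53WT 2 and that at 36676300 in CASM34 2. MIR34AHG and LNCTAM34A share a peak on chromosome 1 with its summit at 9182270 in p53WT 2 and 9182243 in CASM34 2. All 4 genes of p53WT 2 thus rest on 2 peaks, while the permutation test treats genes as independent. The same 4 genes share peaks in CASM34 2, where PVT1 and LINC-PINT had peaks with a −log10 q of 1.66 and 1.81. With lists of equal length the non-coding list had 2 genes in p53WT 2 and 4 in CASM34 2 (adjusted permutation p = 0.252 and 0.0013). Those 4 genes of CASM34 2 again rest on 2 peaks. The arrest list then had 1 gene in p53WT 2 and 3 in CASM34 2 (adjusted permutation p = 0.926 and 0.0746). The apoptosis list had 3 in CASM34 2 (adjusted permutation p = 0.0746).

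Lists not made of direct p53 targets also had peaks. Housekeeping and ribosomal genes, such as EEF1A1 and PPIA (chosen after their values were seen), passed with 8 of 30 in p53WT 2 (adjusted permutation p = 0.0436) and 7 of 30 in CASM34 2 (adjusted permutation p = 0.0153). With lists of equal length they were 1 of 30 against 0.843 expected in p53WT 2 (adjusted permutation p = 0.935) and 4 of 30 in CASM34 2 (adjusted permutation p = 0.0451). At a −log10 q of at least 3 they were 1 and 4 of 30 (adjusted permutation p = 0.874 and 0.0801). Heat shock and immediate early genes had 6 and 5 of 23 (adjusted permutation p = 0.0827 and 0.065), and cell cycle genes repressed through the DREAM complex had 8 and 4 of 35 (adjusted permutation p = 0.189 and 0.614). Lung genes had 4 and 2 of 24 (adjusted permutation p = 0.516 and 0.765), liver genes 2 and 1 of 20 (adjusted permutation p = 0.781 and 0.887), and neuron genes 1 and 1 of 20 (adjusted permutation p = 0.962 and 0.893). The remaining lists of direct p53 targets did not pass at 10 kb. Among them DNA repair genes had 4 and 3 of 20 (adjusted permutation p = 0.516 and 0.576), metabolic targets 6 and 4 of 20 (adjusted permutation p = 0.0995 and 0.193), and other high-confidence targets 8 and 5 of 55 (adjusted permutation p = 0.598 and 0.765). In p53WT 2 metabolic targets passed within 2 kb (adjusted permutation p = 0.0341) and by the nearest-gene rule (adjusted permutation p = 0.0403), and DREAM genes passed within 2 kb (adjusted permutation p = 0.0455). Heat shock and immediate early genes passed within 50 kb in CASM34 2 (adjusted permutation p = 0.0296). None of the 13 lists passed in p53WT 1 or CASM34 1, where the lowest adjusted permutation p was 0.052, for 3 of 30 housekeeping genes in CASM34 1; with lists of equal length this list passed there with 3 genes (adjusted permutation p = 0.0364).

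**Figure D3:**
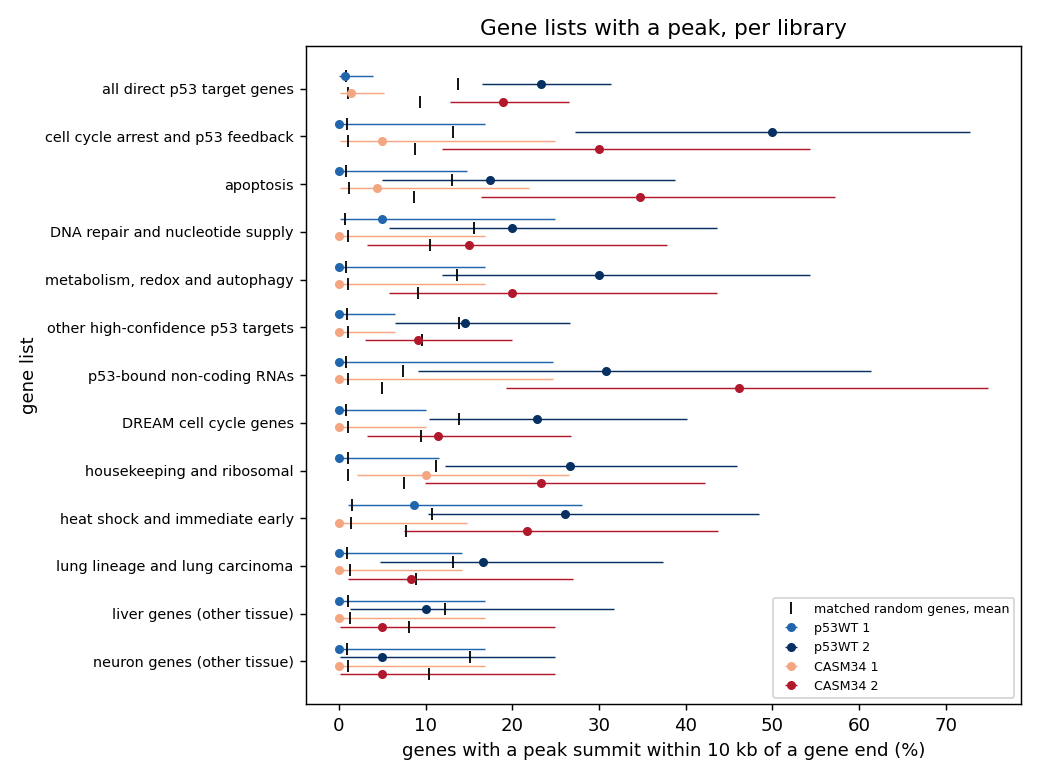
Percent of the genes of each list (vertical axis) with a peak summit within 10 kb of a gene end (horizontal axis), with exact 95% intervals, in each of the 4 libraries; black ticks give the mean of matched random genes. The arrest and feedback list has 10 of its 20 genes called in p53WT 2 and 6 in CASM34 2.

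Direct targets could hardly separate the groups under the rule that both libraries of a group and neither of the other call it. As p53WT 1 called 1 of them and CASM34 1 called 2, at most 1 gene could be p53WT-specific and 2 CASM34-specific, and the counts of 0 and 0 do not compare the groups. A p53WT-specific region, chosen after its values were seen, did lie at REV3L, a direct target on the DNA repair list (chromosome 6, 111483367 to 111483562, 254 bp from the gene end). However, CASM34 2 had another summit at 111482737, 974 bp from that end. The lowest rank percentile of the REV3L region in the p53WT lists was 8.04. Over all protein-coding genes the counts were 23 and 15 (exact binomial p = 0.256). Between the libraries numbered 2 they were 1892 and 1015 (exact binomial p = 2.93e-60), where p53WT 2 also has the longer list, and between those numbered 1 they were 115 and 150 (exact binomial p = 0.0365). Both libraries numbered 2 called 15 direct targets, against 6.07 expected from independent calls (2.47 times, exact hypergeometric p = 2.27e-05), while all protein-coding genes shared 876 against 261.2 (3.35 times). Of the other direct targets, 17 were called in p53WT 2 alone and 11 in CASM34 2 alone (exact binomial p = 0.345). Apoptosis genes split 2 against 6 and arrest genes 6 against 2 (exact binomial p = 0.289 each, adjusted p = 0.929 each). These tests take an even split as the null, while all protein-coding genes split 1892 against 1015. Direct targets and arrest genes lean the same way as that background, and apoptosis genes lean the other way. No list was tested against that background split.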

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

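All tests in this part were chosen after the results were seen. Peaks outside chromosomes 1 to 22, X and Y were left out of the comparisons, and every library had them: 221 in p53WT 1, 398 in p53WT 2, 249 in CASM34 1 and 310 in CASM34 2. These peaks formed 548 regions, of which 137 were called in all 4 libraries, 5 were p53WT-specific and 14 CASM34-specific. No biological explanation was tested for them.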

How the results depend on the processing

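Alternatives that leave out peaks far from genes, use whole genes or use the libraries numbered 2 alone were chosen after seeing the data. Of 93 values recomputed for the main results, 67 were labelled kept, 18 moved, 7 reversed and 1 under the threshold. The 67 include overlap differences of changed sign and target counts too near 0 to decide. Direct targets of p53WT 2 within 50 kb stayed by unadjusted permutation p alone. At a −log10 q of at least 5 the difference in peak number turned to -5.5 and the direct targets of p53WT 2 fell to 2 against 2.00 among random genes (permutation p = 0.596); the cause was not tested. With lists of equal length the peak difference is 0 by construction, and the direct targets of p53WT 2 were 5 (permutation p = 0.384). The p53WT-specific and CASM34-specific regions were 52 and 55 at a −log10 q of at least 3, and 30 and 35 at 5. They were 51 and 61 with equal lists and 24 and 20 without peaks far from genes. The gene-end difference turned to 0.28 and 1.24 percentage points at −log10 q of at least 3 and 5. Leaving out 1 library gave peak differences from -857.5 to 2499.5, gene-end differences from -15.7 to 15.1 points (15.05 without p53WT 1 and 14.5 without CASM34 2), 163 to 3318 p53WT-specific and 145 to 1640 CASM34-specific regions, and direct targets by group from -11 to 17; with 1 library in a group these have no test. The split by number separated more regions than the other splits under every alternative tried, 147 against 65 and 66 at a −log10 q of at least 5. The pairs numbered 2 and 1 alone gave 233 and 102 regions at a −log10 q of at least 3. They gave 68 and 79 at 5, 125 and 158 with equal lists and 364 and 104 with an overlap of 50%. Of 7 calls for single lists, 5 held at a −log10 q of at least 3, 1 at 5, 2 with equal lists and 2 within 50 kb. The call held at 5 was that of non-coding RNAs in CASM34 2, whose 4 genes rest on 2 peaks. Over all settings 5 calls were gained, 1 of them outside the libraries numbered 2. In p53WT 2 housekeeping genes fell to 1 of 30 at a −log10 q of at least 3, and arrest genes to 0 of 20 at 5. Depth was unknown throughout.

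The labels do not say that a number marks a shared batch, and 2 numbers are too few to read a pairing from. With the replicate number as a block, direct targets differed by 5, 18 against 13 (exact binomial p = 0.473), and no list of genes changed its call. Over all protein-coding genes the call changed, with 2007 against 1165 (exact binomial p = 5.29e-51) in place of 23 against 15 (p = 0.256). That lead is from number 2, where p53WT 2 has the longer list, while number 1 had 115 against 150. Alternatives for p53 response elements were not run. The nearest-gene rule gives no value for non-coding RNAs.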

Other observations

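All tests in this part, and the bounds that decided them, were chosen after the results were seen. Windows of 1 Mb with 10 or more peaks held 1011 peaks (63.0% of the list) in p53WT 1, 1025 (20.7%) in p53WT 2, 1068 (62.4%) in CASM34 1 and 764 (23.8%) in CASM34 2. SESN1, a p53-induced stress gene and chosen after its values were seen, carried a peak inside the gene on chromosome 6 in p53WT 1, p53WT 2 and CASM34 2, with summits at 109009384, 109009421 and 109009309. AEN, an apoptosis-enhancing nuclease gene also chosen after its values were seen, had summits at 88621446 and 88621433 on chromosome 15 in p53WT 2 and CASM34 2. These summits lie over 10 kb from the ends of their genes and were not counted as calls. SESN1 was still called in CASM34 2, by another summit at 109094705, 141 bp from its end.

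Longer lists do not account for all of the higher share of gene-end peaks in the libraries numbered 2. With equal lists their shares fell from 34.4% and 34.2% to 21.5% in each. The lowest share there was still 5.39 times the highest share of the libraries numbered 1. At a −log10 q of at least 5 the shares were 13.1% in p53WT 2 and 10.9% in CASM34 2. In p53WT 1 and CASM34 1 they were then 1.68% and 1.45%. Dilution by peaks far from genes does not account for all of it either, since without them the ratio was 2.92. The p53 form is the same within a group, so by design it sets no difference between libraries of a group, and no biological explanation was tested. A preparation batch that follows the number may be the source, but among regions far from genes the number separated 1.57 times as many regions as the next split, 170 against 108, which does not decide, and the labels name no batch. Depth and antibody yield were not tested and stay open.

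Direct p53 targets exceeded matched genes in the libraries numbered 2, and a general signal at the ends of active genes is a candidate explanation. Set against DREAM, housekeeping and immediate early genes, the odds ratio of direct targets was 0.914 (95% interval 0.470 to 1.80) in p53WT 2 and 1.05 (0.504 to 2.26) in CASM34 2, by Fisher exact tests with p = 0.873 and 1. Binding by p53 is not excluded by these wide intervals. The lung, liver and neuron lists, which had lower shares of called genes in both libraries, were left out of this reference. An odds ratio near 1 thus depends partly on that choice. Whether the reference genes are active in these cells was not measured. For arrest and feedback genes the odds ratios were 3.0 (95% interval 0.967 to 9.16, p = 0.0335) and 1.93 (0.521 to 6.39, p = 0.235) by Fisher exact tests. Both intervals include 1, and the explanation stays open.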
